A study of Mus musculus with 14 samples.

How the data were processed

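The data were bulk RNA-seq libraries of lymphocytes sorted from the bone marrow of 8-week-old C57BL/6 mice. Per the labels' protocols, 2000 cells were sorted for each sample as immature natural killer cells (iNK; positive for NK1.1, DX5 and CD27, and negative for CD3, CD11b and IL-7Ra) or immature type 1 innate lymphoid cells (iILC1; positive for NK1.1, CD49a and IL-7Ra, and negative for CD3). Full-length cDNA was made with a SMART-Seq v4 kit, which amplifies polyadenylated RNA from very small inputs, and 1 ng of cDNA was tagged with Nextera XT. Neither kit marks the strand of the RNA. Mice labelled Il-15-flox/KO were the controls, and mice that also carried Vav-Cre were the conditional knockouts (cKO).

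The deposited table held raw counts per Ensembl gene, with no normalization, per the file headers. Trimmomatic 0.33, HISAT2 2.1.0, featureCounts of Subread 1.6.5 and the mouse build mm10 were named in the submitters' processing notes. The annotation release, the strand setting and the handling of reads that map to several places were not given in the sources used here. Counts of near-identical genes (the Klra family, Bcl2a1 copies, Ly6c2, the Tmem176 pair) and of overlapping or antisense genes are therefore uncertain. The table listed 46078 gene identifiers, of which 45143 (97.97%) matched a mouse gene symbol. Gene positions are the table's own, on mm10, and no transcript, exon or UTR was resolved by counts per gene. Each of the 14 columns matched 1 sample by its title.

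Total counts were 6238016 to 8013984 per control iNK library, 6254844 to 12572326 per cKO iNK library, 3512796 to 4933284 per control iILC1 library and 5478641 to 10308693 per cKO iILC1 library. Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15, which left 26990 genes. Counts were scaled by TMM factors. Expression is given as TMM-normalised CPM (CPM), mean ± SD over libraries.

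Adjusted p-values came from edgeR 4.0.16 (R 4.3.3), with the quasi-likelihood F test, two-sided, and Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. A single fit held all 14 libraries and 1 mean for each of the 4 groups, so that the groups shared 1 estimate of the spread (10 residual degrees of freedom). The common biological coefficient of variation was 30%. The standard error (SE) of a log2 fold change was derived from its F statistic. The contrasts were cKO against control within each cell type, iILC1 against iNK within each genotype, and the genotype by cell type interaction, coded as the effect in iILC1 minus the effect in iNK.

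The 37 gene lists covered NK and ILC1 biology, cytokine signalling, cell division, metabolism and markers of other bone marrow cells. Each list was tested with camera in limma 3.58.1 on voom log2 CPM, with a preset correlation of 0.01 between genes and adjustment over the 37 lists of a comparison. Camera was repeated with the correlation estimated for each list, and fry was run on the same values. Of the 37 lists, camera called 20 for genotype in iNK, 15 for genotype in iILC1, 21 for the interaction, 20 for cell type in control and 23 for cell type in cKO. With an estimated correlation these became 3, 1, 2, 4 and 6. Counts of members "adjusted over the list alone" used the same edgeR p-values, adjusted within the list.

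Genes were named by a rule. It took up to 6 higher and 6 lower genes with the largest fold change among those past the threshold, with a mean of at least 10 CPM in the higher group and no overlap between the libraries of both groups. Predicted genes, pseudogenes and antigen receptor segments were left out of that part. It added up to 3 called members of each list that was not a marker list of other cells, and Il15, Il2rb, Bcl2, Tbx21, Eomes, Mki67 and Gzmb in every comparison. For the interaction it took the 6 genes with the smallest p. Some members of lists were left out of the text for length, and some genes are not reported here. A gene from outside the rule is said to have been chosen after its values were seen.

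Replicates of a group differed by more than sampling noise in every pair, with a chi-square per degree of freedom of 4.97 to 27.1, so that no library was counted as a copy of another. The labels do not say that the samples of a group came from separate mice, so the p-values measure only the spread between these samples. The groups, designs, gene lists, naming rule and alternatives were set before the data were examined, except for the following alternatives. Receptor genes of smell and pheromone sensing (1345 olfactory and vomeronasal genes) should be silent in lymphocytes, and their summed CPM was used as a measure of background reads and as a covariate. A second added alternative left out the 2 libraries that lay lowest on the first principal component, which also had the least background. Also added was a repeat of the list tests between cell types without Il7r, Itga1, Itga2, Itgam and Cd27, which encode proteins of the sort gates. Alternatives chosen beforehand were RLE scaling, DESeq2 1.42.0, limma-voom with quality weights, no filter, a filter of 5 CPM in 3 libraries, fits of only the groups compared, leaving out the marker genes of other cells with ribosomal and mitochondrial genes, a replicate block, a threshold of 0.01, and each library left out in turn.

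The edgeR step was tested on simulated counts drawn from the observed means and library sizes, with 100 genes changed by each fold. For genotype in iNK, run on 26077 genes, 34% of 2-fold and 70% of 4-fold changes were recovered. For genotype in iILC1 (26061 genes) these shares were 23% and 71%, and for the interaction (26149 genes) 8% and 46%. For cell type in control (25961 genes) they were 25% and 69%, and in cKO (26070 genes) 31% and 80%. Most 2-fold changes were thus missed in the simulation. Far fewer genes changed there than the 1109 and 920 called between the cell types, and the adjustment is stricter when fewer genes change. The shares for cell type may therefore be too low for these data, where Psma4 was called at a log2 fold change of −0.90 in control.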

Results

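The transcriptomes of 2 populations of bone marrow lymphocytes were measured in control mice and in mice bred to lack Il15 in their blood cells. Natural killer (NK) cells and type 1 innate lymphoid cells (ILC1s) are related lymphocytes that kill target cells or release cytokines without a rearranged antigen receptor, and interleukin 15 (IL-15) is the cytokine that sustains them. The immature stages of both were sorted. Control mice carried a floxed and a knockout allele of Il15. In the cKO mice the Vav-Cre transgene, which is active in blood-forming cells and their progeny, was added to delete the floxed allele. The groups were control iNK (n = 3), cKO iNK (n = 4), control iILC1 (n = 3) and cKO iILC1 (n = 4), with total counts of 3512796 to 12572326 per library. The control iILC1 libraries were the shallowest, at 3512796 to 4933284 counts.

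The first principal component held 28.6% of the variance and the second 13.8%. Receptor genes for odours and pheromones, which lymphocytes should not use, summed to 1637 ± 737 CPM (SD, n = 3) in control iNK, 2128 ± 669 CPM (SD, n = 4) in cKO iNK, 3008 ± 837 CPM (SD, n = 3) in control iILC1 and 2546 ± 923 CPM (SD, n = 4) in cKO iILC1. This background was highest on average in the control iILC1 libraries, and it overlapped between all 4 groups. Libraries with more background mostly lay higher on the first component, from −98.97 in control iNK replicate 1 (1110 CPM) to 80.45 in control iILC1 replicate 2 (3741 CPM). The 2 libraries lowest on it, control iNK replicate 1 and cKO iILC1 replicate 1 (1252 CPM), also had the least background. The TMM factor was lowest in control iNK replicate 1 (0.801) and highest in control iILC1 replicate 2 (1.244).

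**Figure D1:**
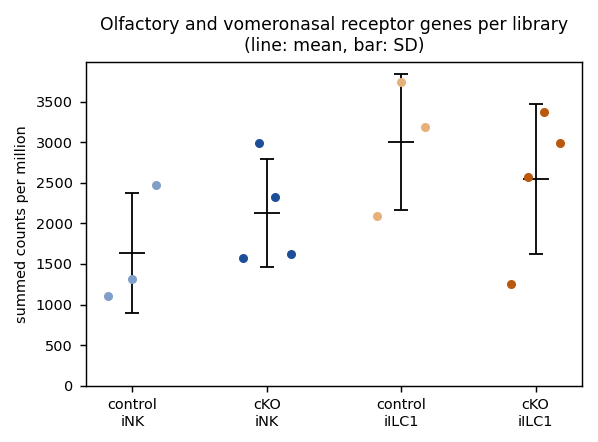
Summed CPM, without TMM scaling, of 1345 olfactory and vomeronasal receptor genes in each library (points). Genotype and cell type are on the x axis, with the mean and SD of each group. The groups overlap, from a mean of 1637 CPM in control iNK to 3008 CPM in control iILC1.

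Il15, the targeted gene (ENSMUSG00000031712, chromosome 8, 82331637 to 82403222, minus strand), was low in every group. It averaged 9.85 ± 1.52 CPM (SD, n = 3) in control iNK and 10.6 ± 1.55 CPM (SD, n = 4) in cKO iNK, with a log2 fold change of 0.11 (SE 0.285, adjusted p = 0.955). In iILC1 it averaged 12.9 ± 1.07 CPM (SD, n = 3) in control and 18.02 ± 5.62 CPM (SD, n = 4) in cKO, with a log2 fold change of 0.48 (SE 0.285, adjusted p = 0.982). The count per gene sums over all exons and does not resolve the floxed part, and both genotypes carried a knockout allele, so these values check neither the deletion nor the labels. Per kilobase of exon, Il15 lay at 5.16, 5.56, 6.78 and 9.44 CPM in control iNK, cKO iNK, control iILC1 and cKO iILC1, against 95th percentiles of 3.56, 4.46, 4.84 and 4.79 CPM for the silent receptor genes.

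The comparison of cKO with control iNK cells addressed how these cells differed in mice bred to lack IL-15 from blood cells. Gzmb, Gzma, Cish and Mki67 were lower in cKO iNK cells, and Cd74, H2-Aa and Cd79a were higher. Gzmb, which encodes the granule protease granzyme B (chromosome 14, 56258856 to 56262260, minus strand), averaged 135 ± 20.2 CPM (SD, n = 3) in control and 21.5 ± 5.69 CPM (SD, n = 4) in cKO, a log2 fold change of −2.65 (SE 0.234, adjusted p = 1.38e-08). Gzma, for granzyme A (chromosome 13, 113093825 to 113100979, minus strand), fell from 1691 ± 334 to 626 ± 95.8 CPM, a log2 fold change of −1.43 (SE 0.238, adjusted p = 0.00108). Of 26990 genes tested, edgeR's quasi-likelihood test called 110, 40 higher and 70 lower in cKO. Over all genes tested, the 3 control and 4 cKO libraries did not overlap in 8.84%, where chance gives 5.71%. The share of higher genes was 36.4%, against 46.9% of 463 with the background covariate and 23.8% of 294 with DESeq2. Without cKO iNK replicate 2 it was 51.8%, with 44 genes higher and 41 lower. The count was 62 without cKO iNK replicate 1 and 64 without cKO iNK replicate 3.

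Genes downstream of IL-15 receptor signalling were among the lower ones. Of 19 genes listed for the response to IL-2, IL-15 and STAT5, the transcription factor that these cytokines activate, 4 fell and the other 15 did not pass. Adjusted over the list alone, 10 were lower and 1 higher. Cish and Socs2, feedback inhibitors of cytokine receptors, changed by −1.52 (SE 0.252, adjusted p = 0.00104) and −1.15 on the log2 scale, with Cish at 19.8 ± 6.50 CPM (SD, n = 3) in control and 6.86 ± 0.198 CPM (SD, n = 4) in cKO. Bcl2l1, which encodes the survival protein BCL-XL, changed by −1.19 (SE 0.226, adjusted p = 0.00565). Gzmb was the remaining member. Camera placed the list lower than other genes (adjusted p = 1.20e-15), with an adjusted p = 0.0571 with an estimated correlation. The Bcl2l1 call was lost without control iNK replicate 1 (adjusted p = 0.0912). Bcl2, a related survival gene, had a log2 fold change of −0.94 (SE 0.238, adjusted p = 0.0799) and was called under 6 alternatives. The receptor chain Il2rb (−0.41, adjusted p = 0.745) and the lineage transcription factors Tbx21 (−0.28, adjusted p = 0.857) and Eomes (0.14, adjusted p = 0.929) did not pass the test, and the estimates of Tbx21 and Eomes changed sign under an alternative (0.03 for Tbx21 with the background covariate, −0.08 for Eomes without control iNK replicate 3).

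All 40 cell cycle genes listed had lower estimates in cKO iNK cells, with a median log2 fold change of −0.79. Individually 6 passed the test (Mki67, Mcm2, Tpx2, Rrm2, E2f1 and Ccne1), and 31 passed when adjusted over the list alone. Mki67, a marker of dividing cells (chromosome 7, 135689788 to 135716379, minus strand), averaged 323 ± 30.7 CPM (SD, n = 3) in control and 139 ± 30.7 CPM (SD, n = 4) in cKO, a log2 fold change of −1.21 (SE 0.27, adjusted p = 0.0292). Mcm2, part of the helicase that opens DNA for replication, changed by −1.05 (adjusted p = 0.0222), and Tpx2, a spindle assembly factor, by −0.97 (adjusted p = 0.0292). Camera gave the list an adjusted p = 2.27e-39, with an adjusted p = 0.0482 with an estimated correlation. Calls of single genes were fragile. Leaving out any of the 7 iNK libraries raised the adjusted p of Mki67 to between 0.0546 and 0.169, and the list had 0 to 5 called members, with 0 when control iNK replicate 3 or cKO iNK replicate 1, 2 or 3 was left out, 2 without control iNK replicate 2 or cKO iNK replicate 4, and 5 without control iNK replicate 1. The filter at 5 CPM also ended the Mki67 call (adjusted p = 0.105). Mcm2 was lost without control iNK replicate 3 or cKO iNK replicate 1, 2 or 3 (adjusted p of 0.0529 to 0.118), and Tpx2 in all leave-outs but that of control iNK replicate 1 (adjusted p of 0.0719 to 0.161).

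Of 16 cytotoxic effector genes, 2 fell (Gzmb and Gzma), and 4 were lower and 1 higher when adjusted over the list alone. Camera gave an adjusted p = 6.41e-07, with an adjusted p = 0.229 with an estimated correlation. Ifng, which encodes interferon gamma, fell with a log2 fold change of −1.63 (SE 0.355, adjusted p = 0.0292), and that call was lost in 5 of 7 leave-outs (adjusted p of 0.108 to 0.216), all but those of control iNK replicate 3 and cKO iNK replicate 4. Other genes with large decreases were S100a6, a calcium-binding protein (−2.53, adjusted p = 5.44e-05), the adhesion G protein-coupled receptor Adgrg5 (−2.13, adjusted p = 7.67e-07), the protease-activated receptor gene F2rl2 (−2.08), Paqr4 (−2.04) and Hopx (−1.69). Adgrg5 fell from 101 ± 9.26 to 23.2 ± 5.60 CPM. Thy1, the surface protein CD90, changed by −1.58, Capg, an actin-capping protein, by −1.47, and Slc7a5, a transporter of large neutral amino acids, by −1.52 (adjusted p = 0.000521). Slc7a5 was the single called member of 22 glycolysis and nutrient uptake genes. Of these, 4 passed when adjusted over the list alone, and camera gave an adjusted p = 2.78e-11, with an adjusted p = 0.178 with an estimated correlation.

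B-lineage and MHC class II genes were among the 40 higher in cKO iNK cells. Of 19 B-cell and plasma cell markers, 10 rose, 15 passed when adjusted over the list alone, and the median log2 fold change was 1.77. Cd74, the MHC class II invariant chain (chromosome 18, 60803848 to 60812646, plus strand), averaged 14.2 ± 3.35 CPM (SD, n = 3) in control and 182 ± 26.7 CPM (SD, n = 4) in cKO, a log2 fold change of 3.68 (SE 0.278, adjusted p = 7.28e-10). H2-Aa, an MHC class II chain, rose by 3.47 on the log2 scale. Cd79a, a signalling chain of the B-cell receptor, rose by 3.59, from 3.02 ± 1.71 to 36.6 ± 13.0 CPM. The IgM receptor gene Fcmr rose by 3.85, and Ly6d, a surface marker of early B-lineage cells, by 3.97. Camera gave the B list an adjusted p = 8.68e-39, with an adjusted p = 0.00064 with an estimated correlation, and a dendritic cell list, whose 4 higher members of 17 were Ly6d, H2-Aa, H2-Ab1 and H2-Eb1, an adjusted p = 0.00064 with an estimated correlation. Of 15 erythroid genes none passed singly in edgeR, where 2139 of all genes had an unadjusted p below 0.05, and 1 was higher and 1 lower when adjusted over the list alone. Their median log2 fold change was 1.30, and camera gave an adjusted p = 9.10e-06, with an adjusted p = 0.229 with an estimated correlation. Of 14 stroma and endothelium genes none passed on either count, their median was 0.39, and camera gave an adjusted p = 0.00499, with an adjusted p = 0.264 with an estimated correlation. The iNK gate demanded NK1.1, DX5 and CD27, which should keep B cells out, and removed cells with CD3, IL-7Ra and CD11b. The labels name no marker for removing B cells.

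Il7r, whose protein the iNK gate excluded, rose from 8.37 ± 2.59 CPM (SD, n = 3) in control to 22.4 ± 5.60 CPM (SD, n = 4) in cKO iNK (log2 fold change 1.42, adjusted p = 0.00565), and the chemokine receptor gene Ccr7, which guides lymphocytes to lymph nodes, rose by 1.41 on the log2 scale (adjusted p = 0.0202). The Il7r call was lost without control iNK replicate 1 or 2 (adjusted p of 0.058 to 0.0666), and the Ccr7 call in 6 of 7 leave-outs (adjusted p of 0.0532 to 0.112), all but that of cKO iNK replicate 2. Il7r was the single called member of 19 lymphoid and ILC progenitor genes. Adjusted over the list alone, 2 of these were higher, and camera gave an adjusted p = 0.000697, with an adjusted p = 0.0571 with an estimated correlation.

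**Figure D2:**
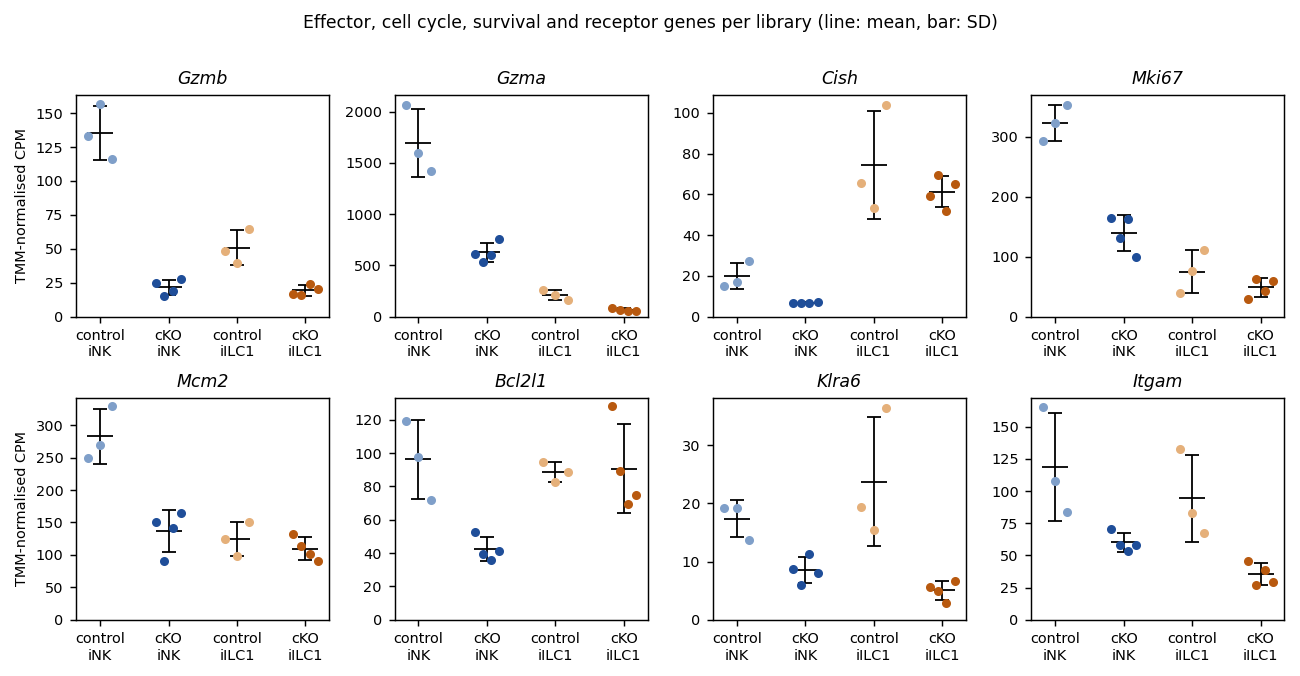
TMM-normalised CPM of 8 genes in each library (points) of the 4 groups on the x axis, with the mean and SD of each group. Within each cell type, Gzmb and Gzma were lower in every cKO library than in every control library. Gzmb averaged 135 CPM in control and 21.5 CPM in cKO iNK, and 50.9 and 19.3 CPM in iILC1.

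The granule proteases Gzma and Gzmb and the receptor genes Klra6 and Klra1 were lower, and MHC class II genes higher, in cKO than in control iILC1 cells, the comparison that asked how iILC1s differed in the same mice. Gzma fell from 209 ± 46.9 CPM (SD, n = 3) to 65.3 ± 14.6 CPM (SD, n = 4), a log2 fold change of −1.68 (SE 0.242, adjusted p = 0.00104), and Gzmb from 50.9 ± 12.9 to 19.3 ± 3.79 CPM, a log2 fold change of −1.41 (SE 0.235, adjusted p = 0.00556). Klra6 and Klra1, of the Ly49 receptor family that senses MHC class I, changed by −2.23 (adjusted p = 0.00104) and −1.38 (adjusted p = 0.0255), with the reads of near-identical Klra genes open to exchange. Of 16 cytotoxic effectors 2 were lower, also 2 when adjusted over the list alone (median 0.04, camera adjusted p = 0.136), and of 33 NK receptors 2 were lower, 8 lower and 1 higher when adjusted over the list alone (median 0.15, camera adjusted p = 0.977). Itgam, the integrin chain CD11b of mature NK cells (chromosome 7, 128062640 to 128128160, plus strand), fell from 94.3 ± 33.9 to 35.3 ± 8.69 CPM (log2 fold change −1.41, adjusted p = 0.00898), and Tmem163, a zinc transporter, by 1.75 on the log2 scale (adjusted p = 0.00294).

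Among the higher genes of cKO iILC1 cells were Cd74 (116 ± 37.5 CPM, SD, n = 3, in control and 326 ± 57.0 CPM, SD, n = 4, in cKO, log2 fold change 1.5, SE 0.245, adjusted p = 0.00462) and the class II chains H2-Aa (1.5), H2-Eb1 (1.45) and H2-Ab1 (1.31). These are 3 of 19 B-cell markers (Cd74, H2-Aa and H2-Ab1) and 3 of 17 dendritic markers, and no other member of either list passed. Psd2, an exchange factor for small GTPases (chromosome 18, 35964830 to 36014715, plus strand), rose most among the genes named by the rule, from 34.8 ± 1.38 to 122 ± 27.2 CPM (log2 fold change 1.81, SE 0.257, adjusted p = 0.00104). In all, 13 genes passed, 6 higher and 7 lower, the others being the predicted gene Gm6472 (higher) and the T cell receptor gene Trac (lower), both outside the naming rule and chosen after their values were seen. Over all genes tested, the control and cKO libraries did not overlap in 5.48%, no more than the 5.71% that chance gives. DESeq2 called 46, with 56.5% higher against 46.2% here. Without the marker genes of other cells and the ribosomal and mitochondrial genes, 22.2% of 9 were higher. That fit removed Cd74, H2-Aa, H2-Ab1 and H2-Eb1, called higher above, and Trac, called lower. Its share of higher genes thus says nothing on the stability of the direction.

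Of 23 genes associated with conventional NK cells, 3 fell in cKO iILC1 (Gzma, Itgam and Klra1) and 7 were lower when adjusted over the list alone. Camera gave an adjusted p = 2.32e-06, with an adjusted p = 0.581 with an estimated correlation. None of the 27 ILC1-associated genes passed over all genes in edgeR, whereas 9 were higher and 1 lower when adjusted over the list alone, and camera gave an adjusted p = 8.59e-07, with an adjusted p = 0.309 with an estimated correlation. None of the 40 cell cycle genes passed either, 2 were lower when adjusted over the list alone, and camera gave an adjusted p = 7.41e-08, with an adjusted p = 0.581 with an estimated correlation. Over all genes, 1203 had an unadjusted p below 0.05. The single list that camera called with an estimated correlation held 16 ILC2 markers (adjusted p = 0.0412), none passing singly and 3 higher when adjusted over the list alone. Of 18 T cell and NKT genes, Trac fell, and 7 were lower when adjusted over the list alone (camera adjusted p = 8.84e-05, and adjusted p = 0.387 with an estimated correlation). Mki67 (−0.63), Il2rb (0.10), Bcl2 (−0.45), Tbx21 (0.51) and Eomes (−0.48) had adjusted p-values of 0.982 to 0.986, and the estimate for Il2rb changed sign under alternatives such as the background covariate (−0.09).

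Calls for genotype in iILC1 changed with single libraries. Without control iILC1 replicate 3, 4 genes passed, and the adjusted p became 0.344 for Cd74, 0.429 for H2-Aa, 0.366 for H2-Eb1, 0.637 for H2-Ab1, 0.13 for Klra6, 0.359 for Gzmb and 0.917 for Klra1. The fold changes there had a size of 1.29 for Cd74, 1.29 for H2-Aa, 1.76 for Klra6 and 1.19 for Gzmb on the log2 scale. Without control iILC1 replicate 1 the adjusted p of Itgam was 0.198, and without cKO iILC1 replicate 4 28 genes passed. H2-Ab1 was lost without any of the 3 control libraries or without cKO iILC1 replicate 3 (adjusted p of 0.054 to 0.637), and H2-Eb1 also without control iILC1 replicate 2 (adjusted p = 0.0533). Klra1 was lost without control iILC1 replicate 1 or 3 or cKO iILC1 replicate 2 or 3 (adjusted p of 0.0885 to 0.917). A split of the 7 iILC1 libraries that followed the background instead of genotype called 119 genes, more than genotype did. Another split that also followed the background called 0. The calls of Psd2, Tmem163 and Gzma held in every leave-out.

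**Figure D3:**
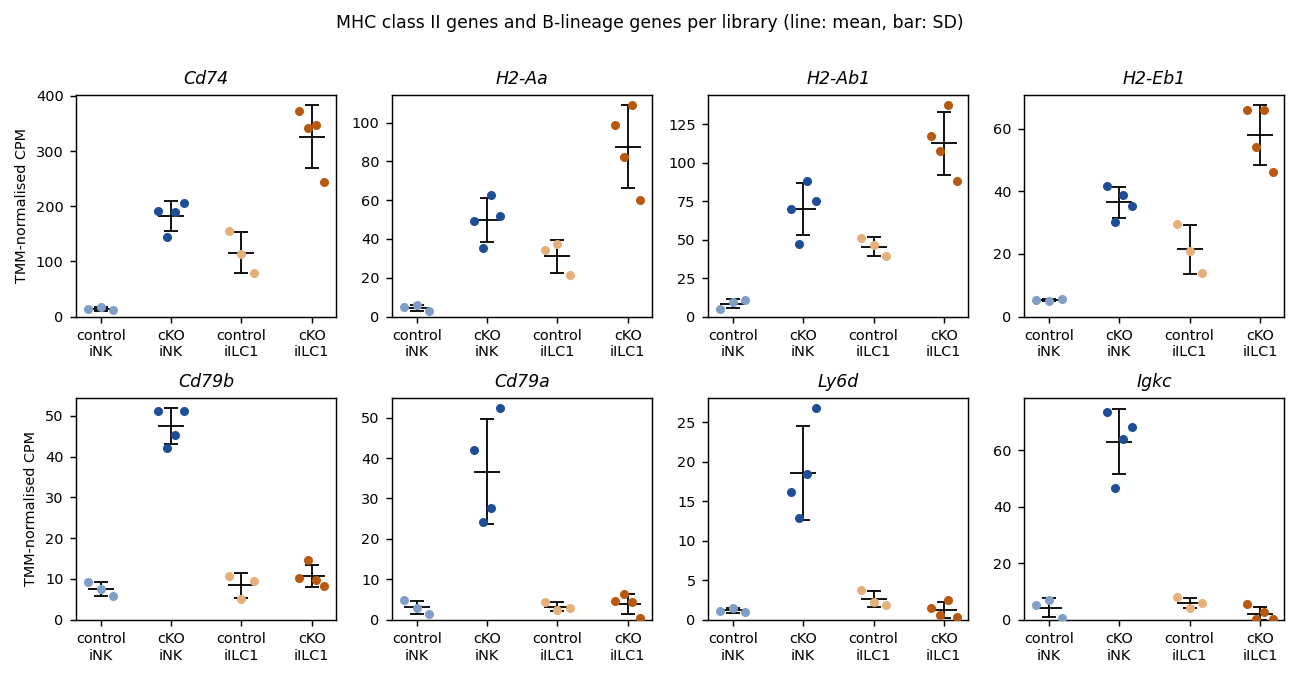
TMM-normalised CPM of 4 MHC class II pathway genes (top) and 4 B-lineage genes (bottom) in each library (points) of the 4 groups on the x axis, with the mean and SD of each group. MHC class II genes were higher in cKO libraries of both cell types, whereas Cd79a averaged 36.6 CPM in cKO iNK and 3.91 CPM in cKO iILC1.

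The calls of both cell types overlapped in 7 genes. Cd74, H2-Aa, H2-Ab1 and H2-Eb1 were higher in both, where independent lists would share 0.00889 genes, and Gzma, Gzmb and Tmem163 lower in both, where they would share 0.0182. The 2 comparisons had no library in common, but the labels do not say whether both cell types came from the same mice, so the lists need not be independent. Across all genes, which are not independent replicates, the log2 fold changes of both comparisons had a Pearson correlation of −0.077.

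**Figure D4:**
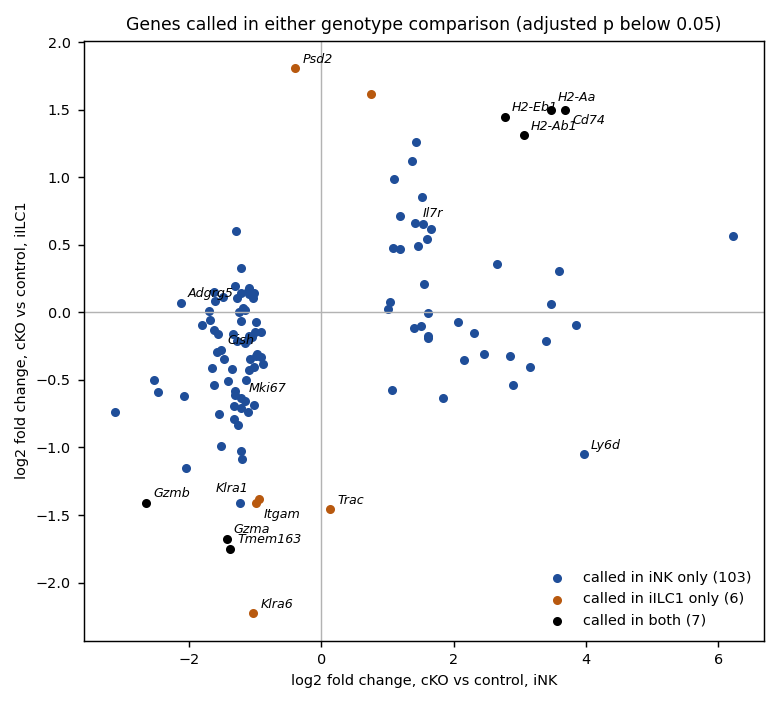
Log2 fold changes of cKO against control in iNK (x axis) and iILC1 (y axis) for each gene called in either comparison (points), 103 in iNK alone, 6 in iILC1 alone and 7 in both. The shared genes are 4 of the MHC class II pathway (upper right) and Gzma, Gzmb and Tmem163 (lower left).

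The effect of genotype differed between the cell types in 21 genes by the interaction test, 6 with a more positive effect in iILC1 and 15 with a more negative one. Ly6d had an interaction of −5.02 on the log2 scale (SE 0.697, adjusted p = 0.00057) and Spib, a transcription factor of B and plasmacytoid dendritic cells, of −3.55 (adjusted p = 0.00452). Spib averaged 2.97 ± 1.11 CPM (SD, n = 3) in control iNK, 26.6 ± 13.9 CPM (SD, n = 4) in cKO iNK and 3.72 ± 0.966 CPM (SD, n = 4) in cKO iILC1. Scd1, a desaturase of fatty acids, had −3.43 (adjusted p = 0.00218), and Cd74, which rose in both cell types, −2.18 (adjusted p = 0.00261). That Cd74 difference is one of ratios, from a lower control mean in iNK. In CPM its gain was 168 in iNK and 211 in iILC1, so the absolute gain was not smaller in iILC1. Adgrg5 had 2.20 (adjusted p = 0.00126), at 244 ± 33.5 CPM in control and 256 ± 62.7 CPM in cKO iILC1, where it did not pass. Of the B list, 6 of 19 genes passed with a more negative effect in iILC1, 15 when adjusted over the list alone, and camera gave an adjusted p = 1.23e-22, with an adjusted p = 0.00544 with an estimated correlation. Of 17 dendritic markers 3 passed with a more negative effect (Ly6d, H2-Ab1 and H2-Aa), 5 when adjusted over the list alone, and camera gave an adjusted p = 1.75e-06, with an adjusted p = 0.00544 with an estimated correlation. For the STAT5 response list, none of 19 passed in edgeR, where 1863 of all genes had an unadjusted p below 0.05. Adjusted over the list alone 5 had a more positive effect in iILC1, and camera gave an adjusted p = 2.23e-08, with an adjusted p = 0.354 with an estimated correlation. For the cell cycle list no member passed in edgeR on either count, and camera gave an adjusted p = 2.83e-06, with an adjusted p = 0.51 with an estimated correlation. Leaving out cKO iNK replicate 1 or 3, or control iILC1 replicate 2 or 3, lowered the count to 12, 13, 11 and 9, while the 5 genes named held in every leave-out. Another drawn split of the libraries called 786 genes. DESeq2 called 37 genes, with 48.6% more positive in iILC1 against 28.6% here.

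Control iILC1 cells were compared with control iNK cells to ask how the lineages differ in mice without Vav-Cre. The iILC1 cells had more transcripts of ILC1-associated genes and of the cytokine genes Tnf and Lta, and fewer of granule proteases, Ly49 receptors and cell cycle genes. Cxcr6, a chemokine receptor of tissue-resident lymphocytes, averaged 9.68 ± 6.04 CPM in iNK and 330 ± 156 CPM in iILC1 (SD, n = 3 each), a log2 fold change of 5.09 (SE 0.585, adjusted p = 7.02e-05). Of 1109 genes called, 255 (23.0%) were higher and 854 lower in iILC1, and the median of all genes lay at 0.16. With the background covariate 943 genes were called, 607 of them shared, with 47.2% higher and a median of −0.002, so the balance of directions changed with that covariate. The count also moved with single libraries, to 491, 657 and 1787 without control iNK replicate 1, 2 and 3, and to 400 and 493 without control iILC1 replicate 2 and 3.

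Of 27 ILC1-associated genes, 14 rose and 1 fell (17 and 1 adjusted over the list alone), with a camera adjusted p = 5.22e-20, and an adjusted p = 0.0185 with an estimated correlation. Without the genes of gate proteins, 12 of 25 rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 1.01e-15, and adjusted p = 0.0293 with an estimated correlation). Ckb, a creatine kinase, rose by 5.35, Tmem176a by 4.79, Tmem176b by 4.49 and Zfp683, the transcription factor HOBIT, by 2.84 on the log2 scale. Tnfrsf25, the death receptor that binds TL1A, rose by 4.92. Il7r, Itga1 and Itga2 followed the sort gates and are no finding here. STAT5 targets went both ways, with Socs2 (2.09), Cish (1.91), Il2ra (1.98) and Lta (2.95) higher and Gzmb (−1.41) lower of 19, and 4 higher and 3 lower when adjusted over the list alone. The list's mean was 0.15 and its median −0.29 (0.28 with the background covariate), and camera gave an adjusted p = 0.732. Tnf rose by 1.73 (adjusted p = 0.00828).

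Of 23 conventional NK genes, 13 fell and 1 rose (18 and 1 adjusted over the list alone), and camera gave an adjusted p = 4.61e-23, with an adjusted p = 0.0559 with an estimated correlation. Without the genes of gate proteins, 12 of 21 fell and 1 rose (17 and 1 adjusted over the list alone; camera adjusted p = 1.81e-22, and adjusted p = 0.0455 with an estimated correlation). Klra4 fell from 690 ± 133 to 22.9 ± 4.39 CPM (SD, n = 3 each; log2 fold change −4.90), Klra8 by 3.93 and Klra3 by 1.87 on the log2 scale. Eomes, the transcription factor that marks NK cells, fell from 732 ± 215 to 132 ± 17.0 CPM (log2 fold change −2.47, adjusted p = 4.20e-07), and Tbx21, shared by both lineages, had −0.20 (adjusted p = 0.715), or 0.45 with the background covariate. Myb changed by −2.32 and Prdm1 by −1.44. Among 16 cytotoxic effectors 9 fell, including Gzma (−3.02) and Gzmk (−3.34), and Tnfsf10, the death ligand TRAIL, rose (10 and 1 adjusted over the list alone; camera adjusted p = 2.77e-10, and adjusted p = 0.133 with an estimated correlation). Among the genes named by the rule, Clip3 (−4.45), Klhl30 (−4.20), Mcam (−3.78) and Col8a2 (−3.51) had the largest decreases outside the lists. Ly6c2, the single higher member of the conventional NK list, rose by 3.32.

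Of 40 cell cycle genes 37 were lower in control iILC1 (39 adjusted over the list alone; median −1.45; camera adjusted p = 2.90e-47, and adjusted p = 0.0203 with an estimated correlation). Mki67 averaged 323 ± 30.7 CPM in iNK and 74.9 ± 35.9 CPM in iILC1 (SD, n = 3 each; log2 fold change −2.10, adjusted p = 3.40e-05), and Stmn1 and E2f2 changed by −2.68 and −2.27. Genes of protein synthesis and respiration were also lower, 50 of 90 ribosomal protein genes (84 adjusted over the list alone; camera adjusted p = 1.88e-42, and adjusted p = 0.135 with an estimated correlation) and 27 of 83 nuclear oxidative phosphorylation genes (72 adjusted over the list alone; camera adjusted p = 8.90e-30, and adjusted p = 0.157 with an estimated correlation). With the background covariate 12 ribosomal and 6 oxidative phosphorylation genes were below the threshold, and the call of Ndufs6 (adjusted p = 0.082) was lost. Il2rb (−0.30) and Bcl2 (−0.32) did not pass and changed sign with that covariate (0.23 and 0.05), and Jak1, an IL-15 receptor kinase (−1.04, adjusted p = 0.0471), lost its call (−0.38, adjusted p = 0.182). That call was also lost without control iNK replicate 1 or 2 or control iILC1 replicate 2 or 3 (adjusted p of 0.188 to 0.254).

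Markers of other innate lymphoid cells and of T cells were higher in control iILC1 as well. Of 16 ILC2 markers 5 rose, among them Arg1 and Rora (7 adjusted over the list alone; adjusted p = 0.00375 with an estimated correlation), and of 12 ILC3 markers 4, among them Ahr and the Tmem176 pair (5 adjusted over the list alone; adjusted p = 0.00304 with an estimated correlation). Of 18 T cell and NKT genes 7 rose, among them Cd3e, Cd3g and Trac, and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 6.30e-06, and adjusted p = 0.135 with an estimated correlation). Of 17 monocyte and macrophage genes 4 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.011, and adjusted p = 0.43 with an estimated correlation). Rora, Bcl11b, Il2ra and the Tmem176 pair stand on lists of several lymphocytes.

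**Figure D5:**
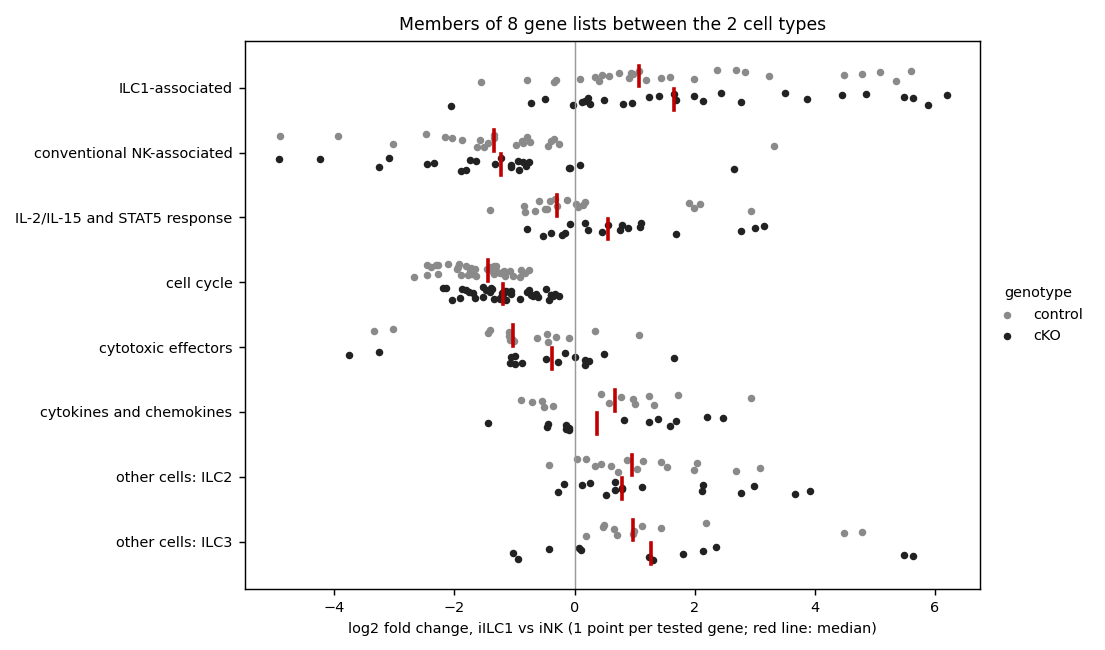
Log2 fold changes of iILC1 against iNK (x axis) for the tested members (points) of 8 gene lists (y axis), in control (grey) and cKO (black), with medians in red. ILC1-associated genes lie mostly above 0 (medians 1.08 in control and 1.66 in cKO) and cell cycle genes below 0 (medians −1.45 and −1.19).

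The cell types were also compared in cKO mice. There were 920 genes called, 471 (51.2%) higher and 449 lower in iILC1, of which 155 higher and 288 lower ones were also called in control, where independent lists would share 4.45 and 14.2. The control and cKO comparisons had no library in common. Of the ILC1-associated genes 17 of 27 rose and 1 fell (18 and 2 adjusted over the list alone; adjusted p = 0.00116 with an estimated correlation). Without the genes of gate proteins it was 15 of 25 with 1 lower (16 and 2; adjusted p = 0.00246 with an estimated correlation). The log2 fold changes had Tnfrsf25 at 6.70, Cxcr6 at 6.19, Ckb at 5.89, Tmem176b at 5.64, Tmem176a at 5.48 and Zfp683 at 4.46. Psd2 rose from 3.77 ± 1.78 CPM in cKO iNK to 122 ± 27.2 CPM in cKO iILC1 (SD, n = 4 each; log2 fold change 5.04, adjusted p = 1.65e-14).

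Several STAT5 targets were higher in cKO iILC1 than in cKO iNK. Of 19 STAT5 response genes 8 rose and none fell (9 and 1 adjusted over the list alone; camera adjusted p = 5.00e-08, and adjusted p = 0.158 with an estimated correlation). Cish averaged 6.86 ± 0.198 CPM in iNK and 61.4 ± 7.66 CPM in iILC1 (SD, n = 4 each; log2 fold change 3.16, adjusted p = 3.91e-11), and Socs2 (3.01), Il2ra (2.77) and Bcl2l1 (1.10) rose with it. Of 6 pro-survival genes 3 rose, Bcl2l1, Bcl2a1d (2.93) and Bcl2a1b (3.16), the last 2 near-identical copies whose reads may have been exchanged (3 adjusted over the list alone; camera adjusted p = 0.00036, and adjusted p = 0.158 with an estimated correlation). The pro-death Bik (4.23) rose too. Of 14 cytokines and chemokines 6 rose, 6 higher and 1 lower when adjusted over the list alone, including Ifng (2.21, adjusted p = 4.94e-05), Tnf (2.48) and Xcl1 (1.59), with a camera adjusted p = 0.00122, and an adjusted p = 0.325 with an estimated correlation. Of 37 interferon response genes 7 rose, also 7 when adjusted over the list alone, Isg15 by 2.84 on the log2 scale (camera adjusted p = 0.000214, and adjusted p = 0.325 with an estimated correlation).

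Conventional NK genes were lower in cKO iILC1, 18 of 23 with 1 higher (19 and 1 adjusted over the list alone; adjusted p = 0.0183 with an estimated correlation). Without the genes of gate proteins it was 17 of 21 with 1 higher (17 and 1; adjusted p = 0.016 with an estimated correlation). Klra4 (−4.93), Klra8 (−4.24), Eomes (−3.09) and Myb (−2.50) fell, and so did Gzma (−3.26), Gzmk (−3.75), Clip3 (−4.39), Col8a2 (−4.38), Klhl30 (−4.35) and Cox6a2 (−4.39), while Gzmb had −0.17 (adjusted p = 0.969). Of the cell cycle genes 26 of 40 fell (33 adjusted over the list alone; adjusted p = 0.0188 with an estimated correlation), Mki67 from 139 ± 30.7 to 48.6 ± 15.3 CPM (SD, n = 4 each; log2 fold change −1.52, adjusted p = 0.000182). None of 90 ribosomal protein genes passed in edgeR, where 2685 of all genes had an unadjusted p below 0.05. Their estimates were still mostly lower, with 1 of 90 positive and a median of −0.50. Camera gave that list an adjusted p = 5.24e-21, with an adjusted p = 0.323 with an estimated correlation. Of 83 oxidative phosphorylation genes 1 fell, Cox6a2, and 11 estimates were positive (median −0.20). Camera gave an adjusted p = 2.05e-05, with an adjusted p = 0.618 with an estimated correlation. Of the B list 2 rose (H2-Aa and Cd74) and 7 fell (3 and 9 adjusted over the list alone; adjusted p = 0.027 with an estimated correlation). Of ILC2 markers 7 of 16 rose (10 adjusted over the list alone; adjusted p = 0.000126 with an estimated correlation), and of ILC3 markers 7 of 12 (7 higher and 1 lower adjusted over the list alone; adjusted p = 0.000381 with an estimated correlation). Of monocyte and macrophage genes 7 of 17 rose and 2 fell (10 and 2 adjusted over the list alone; adjusted p = 0.0865 with an estimated correlation). Il2rb (0.20), Bcl2 (0.17) and Tbx21 (0.59, adjusted p = 0.369) did not pass, although Tbx21 passed with the background covariate (0.71). With that covariate 1798 genes were called, 53.7% of them higher. The share was 37.8% with limma-voom, 39.2% without the 2 libraries lowest on the first principal component and 41% without cKO iILC1 replicate 1, so the balance of directions was not stable. Leave-outs gave 716 to 1107 genes and lost 1 named call, that of Jak1 (adjusted p of 0.063 to 0.064 without cKO iNK replicate 1 or cKO iILC1 replicate 3).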

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

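The splits of the 5 comparisons were planned, whereas the split with the background covariate and the tests of B cells, NK share, dendritic cells, dilution and background were chosen after the results were seen. The NK share test took 4 forms. The first used cells that CD3 and CD11b remove, the second pooled 3 lists (median 0.42, SD 1.54) and did not decide, the next took the lists one by one without regard to their level, and the last, given here, asked first whether their genes lay above background.

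In 11 of 148 groups of 4 libraries tested, 1 library lay far from the others, where chance gives about 1 in 20. In cKO iNK these were replicate 4 for Cish (7.15 CPM against 6.73 to 6.79) and Ifng (9.88 against 4.44 to 4.81), replicate 2 for Tpx2 (30 against 37.2 to 38.2), Ccr7 (16.5 against 33.2 to 36.4) and Bik (0 against 0.256 to 0.306), and replicate 1 for Tnf (4.59 against 1.96 to 2.36). In cKO iILC1 they were replicate 1 for Gzma (87.1 CPM against 56.5 to 59.6), Jak1 (2660 against 1640 to 1730), Tnfsf10 (172 against 93.1 to 105) and Zfp683 (90.4 against 37.1 to 44.7), and replicate 4 for Clip3 (10.9 against 4.24 to 5.27).

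The genotype effect of 9 named genes differed between the cell types by the interaction test. On the log2 scale the effect in iILC1 minus that in iNK was −5.02 for Ly6d, −3.94 for Fcmr, −3.55 for Spib, −3.43 for Scd1, −2.18 for Cd74, −1.97 for H2-Aa, −1.75 for H2-Ab1, 2.20 for Adgrg5 and 2.20 for Psd2. For Cd74 the order is reversed in CPM, with a gain of 168 in iNK and 211 in iILC1.

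B-lineage genes were higher in cKO iNK cells. The background covariate left all 10 called B genes below the threshold, against background reads as the whole cause. The 16 B markers outside MHC class II had a median of 1.53 (SD 1.22), but this is the pattern itself, so B cells or their RNA, in a gate that demands NK1.1, DX5 and CD27 and should keep B cells out, cannot be told apart from B-lineage expression within the sorted cells. A lower share of NK cells, which should raise every other cell type alike, cannot be told apart either. Of the erythroid, stroma and megakaryocyte lists, 0 of 3 had most of their genes above the 95th percentile of the silent receptor genes. Their medians, which thus do not decide, were 1.30 (SD 1.85), 0.39 (SD 0.36) and −0.06 (SD 1.04). No erythroid gene passed in edgeR, and camera gave that list an adjusted p = 0.229 with an estimated correlation. Neutrophil genes, with a median of −0.32, belong to cells that the gate also removes by CD11b. A genotype effect on gene expression within iNK cells stays open, as untested.

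MHC class II genes were higher in cKO iILC1 cells. B cells that carried the Cd74 gain would, at the ratio seen in iNK, have raised Igkc, Cd79a and Cd79b by 166 CPM in sum, whereas the sum changed by −0.91 CPM (SE 4.38). That ratio is one of B cells only if B cells gave the iNK gain, which could not be told. The 14 dendritic markers outside MHC class II had a median of −0.12 (SD 0.51), below the gain of about 1.5 that Cd74 and H2-Aa showed. Whether these markers lay above background in iILC1 was not checked, so their median does not rule out dendritic cells. With the background covariate, 4 of 4 MHC class II pathway genes stayed called. A genotype effect on MHC class II in iILC1 cells, or class II-positive cells of another kind, may remain as a hypothesis. The calls were, however, lost without control iILC1 replicate 3 (adjusted p of 0.344 for Cd74, 0.429 for H2-Aa, 0.366 for H2-Eb1 and 0.637 for H2-Ab1, with log2 fold changes of 1.29 for Cd74 and 1.29 for H2-Aa).

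Cell cycle genes were lower in cKO iNK cells, with a median of −0.79 (SD 0.23). RNA of other cells would have lowered all NK transcripts alike, but 8 NK identity genes had a median of −0.15 (SD 0.35). With the background covariate the median was −0.94, against background as the cause. Fewer dividing iNK cells in the cKO mice may be the explanation, as a hypothesis drawn from the same data and not itself tested.

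Other splits of the same libraries asked how often a grouping without regard to the labels called as many genes. A mixed split holds the real difference as spread within its groups, which lowers its calls, so few calls elsewhere cannot exclude chance. In iNK, 1 of 35 splits, the real one, called as many as 110 genes, the highest other calling 2. The share of 1 in 35, under 0.05, is the smallest that these splits can give and makes chance less likely. In cKO mice the cell type split called 920 and the highest other 113, also 1 of 35. For iILC1, 2 of 35 splits called at least 13 genes, so chance was not excluded. The other one called 119 and parted the libraries exactly by background (control replicates 2 and 3 with cKO replicates 3 and 4). Another split exactly by background (control replicate 1 with cKO replicates 1, 2 and 4) called 0, so such a split need not give many calls. With the background covariate the real split called 65 and the highest other 1 (1 of 35). For the interaction, 4 of 100 drawn splits called at least 21 genes, a share just under 0.05 that does not firmly exclude chance. The 3 others called 34, 226 and 786, and so many calls point to some structure of the samples. The split with 786 parted the iNK libraries exactly by background, but not the iILC1 libraries. Other drawn splits with the same iNK grouping called 1 and 0, so the structure was not identified. In control mice the cell type split called 1109 and the highest other 0 (1 of 10), and the splits were too few for a share under 0.05.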

How the results depend on the processing

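The background covariate, the fit without the 2 libraries lowest on the first principal component and the lists without gate genes were chosen after the data were examined, and the other alternatives were planned. Genotype in iNK called 110 genes, and 294 with DESeq2, 235 with limma-voom, 214 with the filter at 5 CPM, 244 with only the groups compared, 189 with the replicate block, 463 with the covariate and 53 at an adjusted p below 0.01 (leave-one-out 62 to 85). Genotype in iILC1 called 13, and 46 with DESeq2, 55 with limma-voom, 30 with no filter, 37 at 5 CPM, 38 with the block, 65 with the covariate and 21 without the 2 libraries (leave-one-out 4 to 28). The interaction called 21, and 37 with DESeq2, 10 without the markers of other cells and the ribosomal and mitochondrial genes, 35 with the block, 37 with the covariate and 10 at 0.01 (leave-one-out 9 to 31). Cell type in control called 1109, and 2180 with DESeq2, 5912 with limma-voom, 1741 with only the groups compared, 1741 with the block and 431 at 0.01 (leave-one-out 400 to 1787). Cell type in cKO called 920, and 1422 with limma-voom, 1798 with the covariate and 593 at 0.01 (leave-one-out 716 to 1107). The stricter threshold accounts for the counts at 0.01. Without the markers of other cells, the interaction fit no longer held called genes such as Cd74, H2-Aa, H2-Ab1, Spib and Ly6d. All 10 of its calls were shared with the main fit. For the other counts the cause was not tested.

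Estimates that changed sign belonged to genes that did not pass. With the covariate these were Tbx21 in iNK (0.03), Il2rb, cKO vs control in iILC1 (−0.091), and Il2rb (0.226), Bcl2 (0.046) and Tbx21 (0.448) between cell types in control. Without the 2 libraries they were Il2rb in iILC1 (−0.116), Tbx21 between cell types in control (0.019), and −0.018 and −0.024 for the results Il2rb, iILC1 vs iNK in cKO, and Bcl2, iILC1 vs iNK in cKO. With limma-voom it was Il2rb in iILC1 (−0.06). Leave-one-out ranges crossed 0 for Il15 (−0.001 to 0.216) and Eomes (−0.079 to 0.308) in iNK, Il2rb in iILC1 (−0.119 to 0.209), Tbx21 between cell types in control (−0.49 to 0.025) and Gzmb between cell types in cKO (−0.286 to 0.001). The cause was not tested. Over single libraries left out, 1053 results of named genes kept direction and side of the threshold, 98 lost and 1 gained the call. Estimating the correlation within each list ended 83 list calls of camera. Without the gate genes, the ILC1-associated and conventional NK lists were called with an estimated correlation in both genotypes, the latter at an adjusted p of 0.0455 in control against 0.0559 with them.

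Whether replicate numbers paired the libraries could not be told, because 3 or 4 libraries per group are too few to rule it out. The replicate block raised the calls in every comparison. For genotype they rose from 110 to 189 in iNK and from 13 to 38 in iILC1, and for the interaction from 21 to 35. For cell type they rose from 1109 to 1741 in control and from 920 to 1113 in cKO. The cause of these rises was not tested. The correlations of deviations between libraries of the same number ran from −0.02 to 0.07 for genotype in iNK, 0.02 to 0.35 in iILC1, −0.02 to 0.24 for cell type in control and −0.09 to 0.14 in cKO, and 0 of 3, 1 of 3, 2 of 3 and 0 of 4 libraries matched their own number best. The control iILC1 libraries were the shallowest, at 3512796 to 4933284 counts. In simulated data, where far fewer genes changed, the cell type comparison in control recovered 25% of 2-fold and 69% of 4-fold changes. What depth alone limited was not tested.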

Other observations

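Further genes that passed in iNK were chosen after their values were seen. Cd247, the CD3 zeta chain that relays signals from NK receptors, fell with a log2 fold change of −1.11 (SE 0.208, adjusted p = 0.00453), from 155 CPM in control (n = 3) to 71.6 CPM in cKO (n = 4). Serpina3g, an inhibitor of cathepsins in activated lymphocytes, fell from 565 to 234 CPM (−1.27, adjusted p = 0.00346), and Lgals3, which encodes galectin 3, from 34.3 to 11.1 CPM (−1.63, adjusted p = 0.0111). Also lower were Lmnb1 at −1.28 (adjusted p = 0.00122), Uhrf1 at −1.16 (adjusted p = 0.0122), E2f8 at −1.30 (adjusted p = 0.0107) and Cdc6 at −1.21 (adjusted p = 0.0266). Siglecg, a sialic acid receptor of B cells, rose by 2.46 (adjusted p = 0.000263), Id3 by 2.31 (adjusted p = 0.000291) and Nrp2 by 1.61 (adjusted p = 8.88e-05). Igkc, the kappa light chain, went from 4.22 ± 3.33 to 63.0 ± 11.7 CPM (SD, n = 3 and 4) without passing (adjusted p = 0.0767).

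Genes for respiration, ribosomes and the proteasome had lower estimates in cKO iNK and higher ones in cKO iILC1. Mean background went the other way, from 1637 CPM in control to 2128 CPM in cKO iNK, and from 3008 to 2546 CPM in iILC1. The estimates are from the fit without the background covariate and do not separate background from genotype. The median log2 fold change of 83 oxidative phosphorylation genes was −0.34 in iNK and 0.27 in iILC1, and camera gave the interaction an adjusted p = 2.35e-19, with an adjusted p = 0.41 with an estimated correlation. No member passed in edgeR in either genotype comparison, where 2139 and 1203 of all genes had an unadjusted p below 0.05. Rora, a transcription factor of ILC development, went from 135 ± 25.0 to 289 ± 67.9 CPM in iILC1 (log2 fold change 1.10, adjusted p = 0.0634) and did not pass.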
